A study of Mus musculus with 2 samples.

How the data were processed

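Total RNA of dorsolateral prostate was extracted with Trizol and 100 ng was labelled with a low-input kit for 2-colour Agilent arrays, per the labels' protocols. Both deposited scanner files came from 1 slide and were made with Feature Extraction 11.0.1.1, per the file headers. The deposited spot and local background signals are median pixel intensities in each dye, neither background-subtracted nor dye-normalized. The processed signals in the same files are intensities that the scanner software background-subtracted and dye-normalized, and the deposited log ratio is log10 of Cy5 over Cy3 of these, per the file headers. Spike-in transcripts gave a slope of 0.869 and 0.868 between observed and expected log ratios on arrays 1 and 2 (r = 0.989 and 0.986), and the linear dye factor for Cy5 was 3.82 on array 1 and 12.7 on array 2, per the file headers.

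The authors' deposited value table holds 8533 rows in log2 units. Its direction, scale and centring were found from the scanner values: each column matched the scanner software's log ratio of transgenic over wild type in log2, with r and slope of 1 on each array, and a median of 0.0000. All of its non-control probes were well above background in both dyes on both arrays. The filter behind the table is not given in the sources used here. The table was used as an alternative.

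The direction of every ratio rests on the dyes in the labels, with array 2 the dye swap of array 1. Signals were analysed with limma 3.58.1 in R 4.3.3. The planned signal was the mean of each spot, and the median was used in its place because the files as used here hold no column of means. Background was corrected by normexp with an offset of 50, and each array was normalized by loess with control and outlier spots at weight 0. Each array held 43379 non-control spots of 41174 probes. Outlier spots, 157 on array 1 and 177 on array 2, were left out, and spots of a probe were averaged. The 245 probes printed 10 times had a median SD of 0.17 and 0.23 in log2 ratio within arrays 1 and 2. No spot was saturated. The number of arrays and the weak Cy5 signal of array 2, with a median net intensity of 10 against 26 on array 1, limit the precision.

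Probes were named by matching their accessions, without versions, to a RefSeq table of assembly GRCm38.p6. A match was found for 27816 probes and 18952 symbols, and 13358 probes had none. The array annotation in the file headers cites another build, so no coordinates are given. A probe was detected when well above background in at least 1 pool on both arrays. A gene took the value of its detected probe with the highest mean intensity, so that other probes of a gene can differ from it.

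A gene was called higher or lower when its log2 ratio reached 1.5-fold in the same direction on each array. As a yardstick of dye effects, the same count was made with array 2 left unturned. No p-values were computed because the arrays repeat the same pair of pools. For 33 gene lists fixed before the data were examined, the median log2 ratio of the detected members was placed among 10000 random lists of the same size matched on mean intensity in 20 bins, if 5 or more genes were detected. These percentiles describe these pools and are no test of genotype. A gene in one pool only has a bound from the lowest signal among probes well above background, or its own signal where higher, after loess and Aquantile normalization. Where its own signal was used, the bound is its mean ratio over the arrays and not a lower limit. The dyes were balanced over the arrays.

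Genes named in the text were, by a rule set before the data were examined, the 12 highest and 12 lowest past the size rule and measured in both pools, up to 4 in each direction detected in 1 pool only, up to 4 members of each list with the largest absolute mean ratio, and 18 genes of prior interest. Not all genes that the rule allows are printed, and a few of the genes of prior interest are not reported here. Further genes are named where a count was small or a feature stood out, and are said to have been chosen after their values were seen.

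The size rule was tested on simulated data for this comparison, with 41150 probes and a dye effect with an SD of 0.34 in log2. It called 14% of 50 probes changed by 1.5-fold, 70% of 50 changed by 2-fold and 100% of 50 changed by 4-fold, with 0 calls in the wrong direction and 0 calls among 16951 unchanged probes. Disagreement between the arrays was simulated as a dye effect, opposite in sign on the turned arrays, with independent noise of 0.17 and 0.23 in SD. Unchanged probes could then hardly pass the rule. The 0 calls therefore do not estimate false calls in the real data, where the arrays were not correlated (r = −0.03). In a simulation on 10434 genes, a list of 12 genes shifted by −1 in log2 fell at percentile 0, and 1 of 60 unshifted lists fell outside the central 95%. The figures were drawn with matplotlib 3.10.9 and tables made with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.

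Alternatives were no background subtraction, an offset of 16, the scanner software's log ratios, median centring, Aquantile or scaling between arrays, no filter or detection in both pools, the mean over probes, the deposited table, each array alone, a 2-fold rule, random lists without matching and lists of at least 8 genes. A count of genes with predicted seed sites in their 3′ UTRs was planned and not run, because no transcript sequences were used here.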

Results

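Gene expression was measured in the dorsolateral prostate of FVB/N mice at 6 months of age. A wild-type pool and a transgenic pool were made, each from 6 animals, the transgenic mice carrying the microRNA miR-32 under ARR2PB, a composite probasin promoter that is active in prostate epithelium and responds to androgen. Both pools were hybridised together on 2 arrays of 1 slide with the dyes exchanged, so that the transgenic pool carried Cy3 on array 1 and Cy5 on array 2. The comparison asks how expression of miR-32 in the mouse prostate alters the transcriptome. Each genotype was represented by 1 pool, so the arrays are technical repeats that count as 1 replicate, no test of genotype was possible, and each ± below is the SD over the 2 arrays. Cy3 signals were well above background at 58.3% and 57% of spots on arrays 1 and 2, and Cy5 signals at 42.1% and 21.1%. A total of 10434 genes were detected, 10424 of them in the wild-type pool on both arrays and 6056 in the transgenic pool on both arrays. The transgenic pool was read in the weakest channel, Cy5 of array 2, so these numbers do not compare the genes expressed in the pools. Many genes thus count as detected through the wild-type pool only.

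Spink1, a Kazal-type serine protease inhibitor secreted by the mouse prostate, was 78.4-fold lower in the transgenic pool (log2 ratio −6.29 ± 0.23, 2 arrays). Sbp, the androgen-dependent spermine-binding protein of prostatic secretion, was 9.06-fold lower (−3.18 ± 0.42), and Spink5, another Kazal-type inhibitor, was lower at −3.17 ± 0.69. The acute phase gene Saa3 was 8.39-fold lower (−3.07 ± 0.54). Aqp8, a water channel, was 6.91-fold higher (2.79 ± 0.61, and 4.90 with the scanner software's log ratios), followed by Ramp1, a subunit of the CGRP receptor, at 2.16 ± 0.47 and the lipase-related gene Pnliprp1 at 2.09 ± 0.29.

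The remaining genes among the 12 lowest were Saa1 at −2.41 ± 0.65, Fabp4 at −2.13 ± 0.22, Cd74 at −2.09 ± 0.47, Sbpl at −2.06 ± 1.14, H2-Aa at −1.99 ± 0.02, Pigr at −1.94 ± 0.07, Saa2 at −1.90 ± 0.40 and H2-Ab1 at −1.74 ± 0.69. The other genes among the 12 highest were Fbxo2 at 1.74 ± 0.78, 1110006O24Rik at 1.67 ± 0.82, Arid5b at 1.64 ± 0.93, Cyp17a1 at 1.62 ± 1.13, Ubap2l at 1.61 ± 0.53, Gm11938 at 1.57 ± 0.58, Ear1 at 1.56 ± 0.03, Hspa4 at 1.56 ± 0.0048 and Khsrp at 1.51 ± 0.17. With median centring, Aqp8 alone of the higher genes named here kept its call, and with the scanner software's log ratios or the deposited table the call of H2-Ab1 ended (0.32 and 0.30 on array 2). Ido1, Reg3b and Defb6 were past the rule and were detected in the wild-type pool on both arrays and in the transgenic pool on neither. Their bounds equalled their mean ratios, so the sizes below are uncertain and are not lower limits. Ido1, which degrades tryptophan and is induced by interferon, was 2.38-fold lower (−1.25 ± 0.21). The antimicrobial lectin Reg3b was 2.32-fold lower (−1.22 ± 0.64) and the defensin Defb6 1.92-fold lower (−0.94 ± 0.23). On array 2 alone the 3 genes were at −1.10, −0.77 and −0.78.

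**Figure D1:**
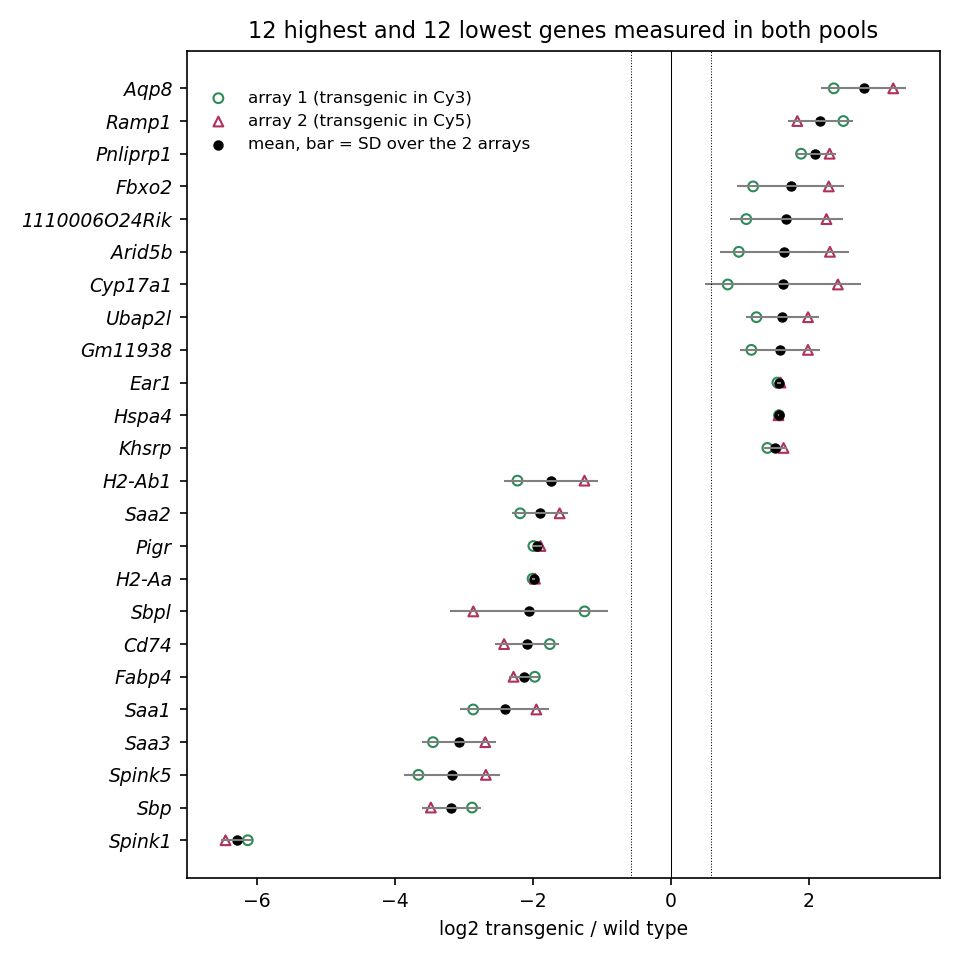
The log2 ratio of transgenic to wild-type pool (horizontal axis) is plotted for the 12 highest and 12 lowest genes measured in both pools, with open circles for array 1, open triangles for array 2, filled points for the mean and bars for the SD over the 2 arrays; dotted lines mark 1.5-fold. Spink1 stood apart at −6.29, while the highest gene, Aqp8, was at 2.79.

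By a size rule of at least 1.5-fold in the same direction on each array, 95 genes were higher and 136 lower in the transgenic pool, together 2.21% of detected genes. At 2-fold the counts were 25 and 37, and at 4-fold they were 1 (Aqp8) and 5 (Spink1, Sbp, Spink5, Saa3 and Cfd). For comparison, 318 genes followed the dye rather than the pool at 1.5-fold, 282 of them brighter in Cy3, against 27 at 2-fold and 1 at 4-fold. Across all detected genes the ratios of the 2 arrays were not correlated (Pearson's r = −0.03, Spearman's rho = −0.12 across genes, which are not independent replicates), whereas r was 0.26 with the scanner software's log ratios and 0.24 in the deposited table. Genes were split 95 higher to 136 lower in the setting used, 94 to 76 among genes detected in both pools, 248 to 625 with the scanner software's own log ratios, 178 to 119 in the authors' deposited value table, and 2 to 554 with median centring, which moved the median of detected genes to −0.57. On array 2 alone the split was 544 to 1570 and on array 1 alone it was 845 to 558.

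Some called genes had more than 1 detected probe, and their probes did not always agree. A probe of opposite sign was present for 8 of 29 such lower genes and for 24 of 39 such higher genes. The other probes of these lower genes had a median log2 ratio of −0.57 against −0.93 for the brightest probes, and those of the higher genes had −0.0033 against 0.93. Among the genes named here, Fbxo2, Arid5b, Ubap2l, Drosha, Tmprss2, Klf2 and Dnajb9 had such an opposed probe. The other probes of Hspa4 had mean ratios of 0.20 and 0.31 and were below 0 on array 2. With the mean over probes the calls of Hspa4 (0.69), Fbxo2 (0.64), Drosha (0.33), Tmprss2 (0.42), Klf2 (0.33) and Dnajb9 (−0.23) ended. H2-Aa, H2-Ab1, H2-K1, Fabp4, Saa1, Jchain and Hspa1a had mean ratios below 0 on each of their detected probes.

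**Figure D2:**
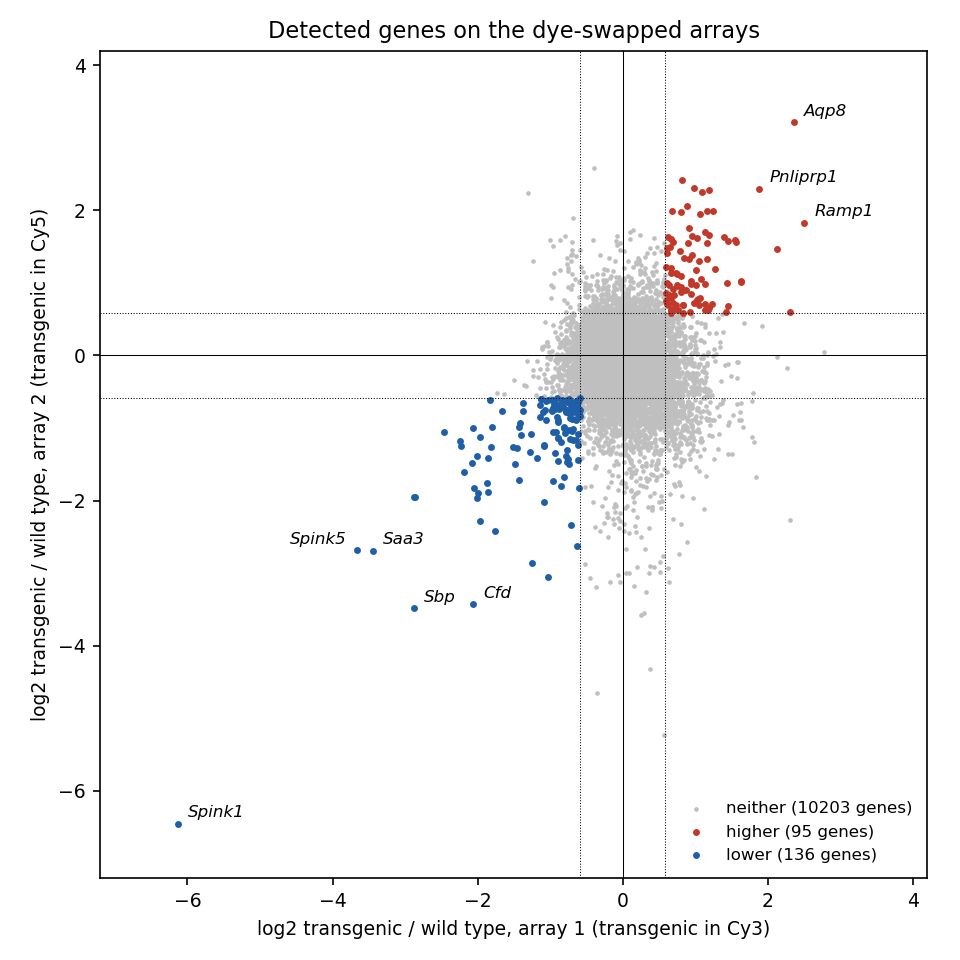
The log2 ratio of transgenic to wild-type pool on array 1 (horizontal axis) is plotted against that on array 2 (vertical axis) for each of the 10434 detected genes, with 95 higher genes in red, 136 lower genes in blue and dotted lines at 1.5-fold. Most genes form a cloud with no slope (r = −0.03), and Spink1 lies alone at the lower left.

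Most prostate secretory and androgen-responsive genes did not pass the rule (12 of 19 and 16 of 20 detected). The share that passed was nevertheless larger in each list than the 2.21% of all detected genes. Spink1, Sbp and Spink5 were the 3 lowest genes with a symbol among those measured in both pools. Of 19 detected prostate secretory products, 6 were lower, 1 was higher (Pnliprp1) and 12 were neither. The lower genes included Spink1, Sbp, Sbpl and Spink5, as well as Msmb, the beta-microseminoprotein of prostatic fluid, at −0.86 ± 0.37. The call of Msmb ended without background subtraction (−0.48), with scaling between arrays, with the scanner software's log ratios and in the deposited table. Probasin (Pbsn), whose promoter drives the transgene, was at 0.54 ± 1.21, and Tgm4, the prostate transglutaminase, at 0.70 ± 0.64, neither past the rule. The median of the list was 0.12 and its mean −0.64, the 2 array medians were −0.08 and −0.30, and the median stood at percentile 91.6 of random lists matched on intensity. This position depended on the processing: it was 1.59 on array 2 alone, 24.6 on array 1 alone and 99.4 with undetected members included. The sign of the median turned with the scanner software's log ratios (−0.14, percentile 3.6), in the deposited table (−0.12, percentile 2.8) and with detection in both pools (−0.02, percentile 22.7). With median centring, where the median of all detected genes was −0.57, it was −0.79 (percentile 85.5). Of 20 androgen-responsive genes, 3 were lower (Spink1, Msmb and Hoxb13), 1 was higher (Tmprss2, 1.12 ± 0.71) and 16 were neither, with a median of −0.06 (percentile 36.8) that was −0.02 and −0.32 on arrays 1 and 2 alone (percentiles 46.8 and 3.0) and −0.19 with the mean over probes (percentile 2.3). The call of Tmprss2 ended with the scanner software's log ratios and in the deposited table (0.57 on array 1 in each), with median centring (0.23) and with the mean over probes. Hoxb13, a prostate homeobox gene chosen after its value was seen, was at −0.69 ± 0.03. Spink1, Msmb, Pbsn, Tgm4 and Azgp1 belong to both lists, so the lists are not independent.

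Acute phase, antigen presentation and interferon-responsive genes were lower together. Of 10 detected inflammatory and acute phase genes, 7 were lower and 3 neither, with a median of −1.47 (−1.47 and −1.35 on the 2 arrays). Besides Saa1, Saa2 and Saa3 these included Lcn2, an iron-sequestering protein of innate defence, at −1.87 ± 0.01. Of 17 detected interferon-responsive and antigen presentation genes, 8 were lower, 9 were neither and all 17 means were below 0, with a median of −0.62. The MHC class II genes H2-Aa and H2-Ab1 were the lowest with Iigp1, an interferon-inducible GTPase (−1.76 ± 1.00), and the MHC class I gene H2-K1 was at −1.07 ± 0.43, a call that ended without background subtraction (−0.41 on array 2). Of 15 myeloid markers, 4 were lower (Cd74, Lyz1, C1qc and Mrc1, the last chosen after its value was seen), 11 were neither and all 15 means were below 0, with a median of −0.55. Lyz1, a lysozyme, was at −1.57 ± 0.21 and C1qc, a complement component, at −0.75 ± 0.23. The call of C1qc ended with the scanner software's log ratios (−0.40 on array 2), in the deposited table (−0.42) and with scaling between arrays (−0.55), and that of Mrc1 with scaling (−0.56 on array 2) and without background subtraction (−0.30). Lcn2, Iigp1, Lyz1, Mrc1, Ccl5 and Jchain were well above background in the transgenic pool on 1 of the 2 arrays. The medians of these inflammatory, interferon and myeloid lists lay below all 10000 matched random lists. With undetected members included, the inflammatory median was −0.07, inside the central 95% (percentile 6.87), and the interferon median −0.30 (percentile 0). Of 7 T and NK cell markers, Ccl5 was lower at −0.74 ± 0.06, a call that ended without background subtraction (−0.57 on array 2), and 6 were neither. The median of these markers was −0.12 (percentile 39.3), −0.34 and −0.25 on arrays 1 and 2 alone (percentiles 1.26 and 20.025) and −0.92 with the scanner software's log ratios (percentile 3.2). Of 3 detected B and plasma cell genes, Jchain, which joins secreted IgA, was lower at −1.94 ± 0.16. Pigr, the epithelial IgA transporter, was the lower member of 7 detected goblet cell and mucin genes, whose median was −0.17 (percentile 12.3). This median was −0.37 and −0.04 on arrays 1 and 2 alone (percentiles 1.22 and 50.3), and −0.30 in the deposited table (percentile 1.985).

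Adipocyte markers were also lower. Of 13 detected, 6 were lower and 7 were neither, with a median of −0.83 (−0.93 and −0.54 on the 2 arrays) that lay below all 10000 random lists. Cfd, the adipsin gene, was at −2.75 ± 0.96, Fabp4, a fatty acid carrier, at −2.13 ± 0.22, Car3 at −2.04 ± 1.43 and Adipoq, the adiponectin gene, at −1.81 ± 0.08. Cfd, Car3 and Adipoq were well above background in the transgenic pool on 1 of the 2 arrays.

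Few epithelial and stromal markers passed the rule. None of 15 luminal and none of 13 basal markers passed the rule, with medians of −0.12 and −0.09 (the luminal median was −0.96 with median centring, at percentile 18.8), and Krt8 was at −0.01 ± 0.19 and Krt5 at 0.06 ± 0.76. Of 12 proximal luminal or progenitor markers, Ly6a (−1.55 ± 0.66), which encodes Sca-1, and Ltf (−0.78 ± 0.12), the lactoferrin gene, were lower and 10 were neither (the call of Ltf ended without background subtraction, −0.39 on array 2), with a median of −0.30 (percentile 0.28). On arrays 1 and 2 alone this median was −0.45 and −0.09 (percentiles 0 and 47.0), so its position rests on array 1, and it was −0.32 with the scanner software's log ratios (percentile 5.0). None of 18 fibroblast and matrix genes passed the rule, while their median of −0.26 lay at percentile 0.15. It was −0.05 and −0.27 on arrays 1 and 2 alone, where it lay inside the central 95% (percentiles 42.9 and 4.55), as it did in the deposited table (−0.03, percentile 46.1) and with median centring (percentile 21.5). No call fell among 10 smooth muscle (median −0.02, Acta2 0.36 ± 0.39), 7 skeletal muscle (0.04), 11 endothelial (−0.04), 7 nerve (−0.19) and 5 urothelial markers (−0.14), all inside the central 95% of random lists. The skeletal muscle list lay above it with the scanner software's log ratios (percentile 98.3), without background subtraction (99.4) and with undetected members included (97.53). It was also above it on array 1 alone (98.0), against percentile 34.0 on array 2. No call was made among 4 neuroendocrine and 2 erythrocyte genes. The single detected seminal vesicle product, Ceacam10, was lower at −1.36 ± 0.14, with Ceacam10 and Ltf well above background in the transgenic pool on 1 of the 2 arrays, and Svs2, Psca, Muc1 and Xist were not detected.

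No shift of the reported or predicted targets of the miR-32 seed family was seen as a group, which does not exclude a small one. Of 25 detected, 24 were neither and 1, the transcription factor Klf2, was higher at 0.93 ± 0.38. The call of Klf2 ended with the scanner software's log ratios (0.26 on array 2), in the deposited table (0.23), with an offset of 16 (0.58), with the mean over probes and with median centring, where its mean was −0.12. The median was −0.02 (percentile 74.7), where the central 95% of matched random lists spanned −0.18 to 0.07. A smaller shift would not stand out, and the size rule called 14% of simulated 1.5-fold changes. Btg2, an anti-proliferative gene, was at 0.07 ± 0.07, Bcl2l11, which encodes the pro-apoptotic protein BIM, at −0.06 ± 0.08, and the phosphatase gene Phlpp2 at −0.35 ± 0.39. Tmem245, the host gene of the endogenous miR-32, was at −0.06 ± 0.28. It reports the endogenous locus and not the transgene, so it does not check the labels, and mature miR-32 was not analysed here. Phlpp2 and Tmem245 were well above background in the transgenic pool on 1 of the 2 arrays. Of 10 detected genes of the miR-32 locus and the microRNA pathway, Drosha, the nuclear microRNA-processing enzyme, was higher at 0.90 ± 0.44 and 9 were neither. The call of Drosha ended with the scanner software's log ratios and in the deposited table (0.34 on array 1 in each), with the mean over probes and with median centring (0.07). The median of these genes was 0.13 (percentile 98.7), and −0.23 with median centring, where it still lay above most matched random lists (percentile 99.9). It was 0.31 and 0.13 on arrays 1 and 2 alone (percentiles 99.2 and 94.8).

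Among stress genes, Hspa5, the chaperone BiP of the endoplasmic reticulum, was lower at −1.18 ± 0.39. Xbp1 (−0.88 ± 0.04) and Dnajb9 (−0.71 ± 0.09), both named after their values were seen, were lower and Asns, asparagine synthetase, was higher (1.39 ± 0.82) among 23 secretory pathway and stress genes, whose median of −0.20 stood at percentile 0.40. On arrays 1 and 2 alone this median was −0.13 and −0.17, inside the central 95% (percentiles 9.95 and 12.7). The heat shock genes Hspa1a (−1.71 ± 0.75) and Dnajb1 (−1.63 ± 1.40) were lower among 13, with a median of −0.27 (percentile 0.57). On arrays 1 and 2 alone it was −0.54 and −0.08 (percentiles 0.03 and 42.9), so its position rests on array 1. None of 14 mitotic and replication genes passed the rule (median −0.18, percentile 6.4), and Mki67 was at −0.18 ± 0.07. With the scanner software's log ratios these values were −0.55 and −0.63. The mitotic list lay below the central 95% on array 1 alone (percentile 0.54, against 18.3 on array 2) and with median centring (2.31). None of 16 p53 targets passed the rule either, with a median of −0.21 (percentile 1.84) that was −0.21 and −0.08 on arrays 1 and 2 alone (percentiles 4.10 and 49.2). This list also lay inside the central 95% with the scanner software's log ratios, in the deposited table, with median centring, with the mean over probes and with an offset of 16. Klf2 was the 1 higher of 14 immediate early genes (median 0.0035), and Tef (−0.93 ± 0.34, a call that ended with the scanner software's log ratios) the 1 lower of 10 circadian clock genes (median −0.17). Tef, Dnajb1 and Mki67 were well above background in the transgenic pool on 1 of the 2 arrays. No call was made among 17 cholesterol synthesis (−0.13), 11 fatty acid synthesis (−0.20), 18 oxidative phosphorylation (−0.06) and 18 ribosomal protein genes (−0.08), and the medians of these and of the immediate early and clock lists lay inside the central 95%. The ribosomal protein list fell below it with the scanner software's log ratios (percentile 0.17), in the deposited table (0.26) and with median centring (0.73). It did so too with an offset of 16 (1.26) and with detection in both pools (2.07). The fatty acid synthesis list fell below it in the deposited table (0.93), with undetected members included (2.18) and with detection in both pools (2.495). The clock list did so on array 2 alone (−0.45, percentile 0.79), against −0.10 (percentile 28.1) on array 1. In all, 10 of 29 lists with 5 or more detected genes lay outside the central 95%, where lists of unrelated genes would give about 1.5. This number was 6 on array 2 alone and 12 on array 1 alone. Lists share genes and genes of a list can vary together, so the excess over 1.5 is no test. Of the 10 lists, 4 lay outside on each array alone, the inflammatory, interferon, myeloid and adipocyte lists, while 3 did so on array 1 alone (proximal luminal, heat shock and microRNA pathway) and 3 on neither.

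**Figure D3:**
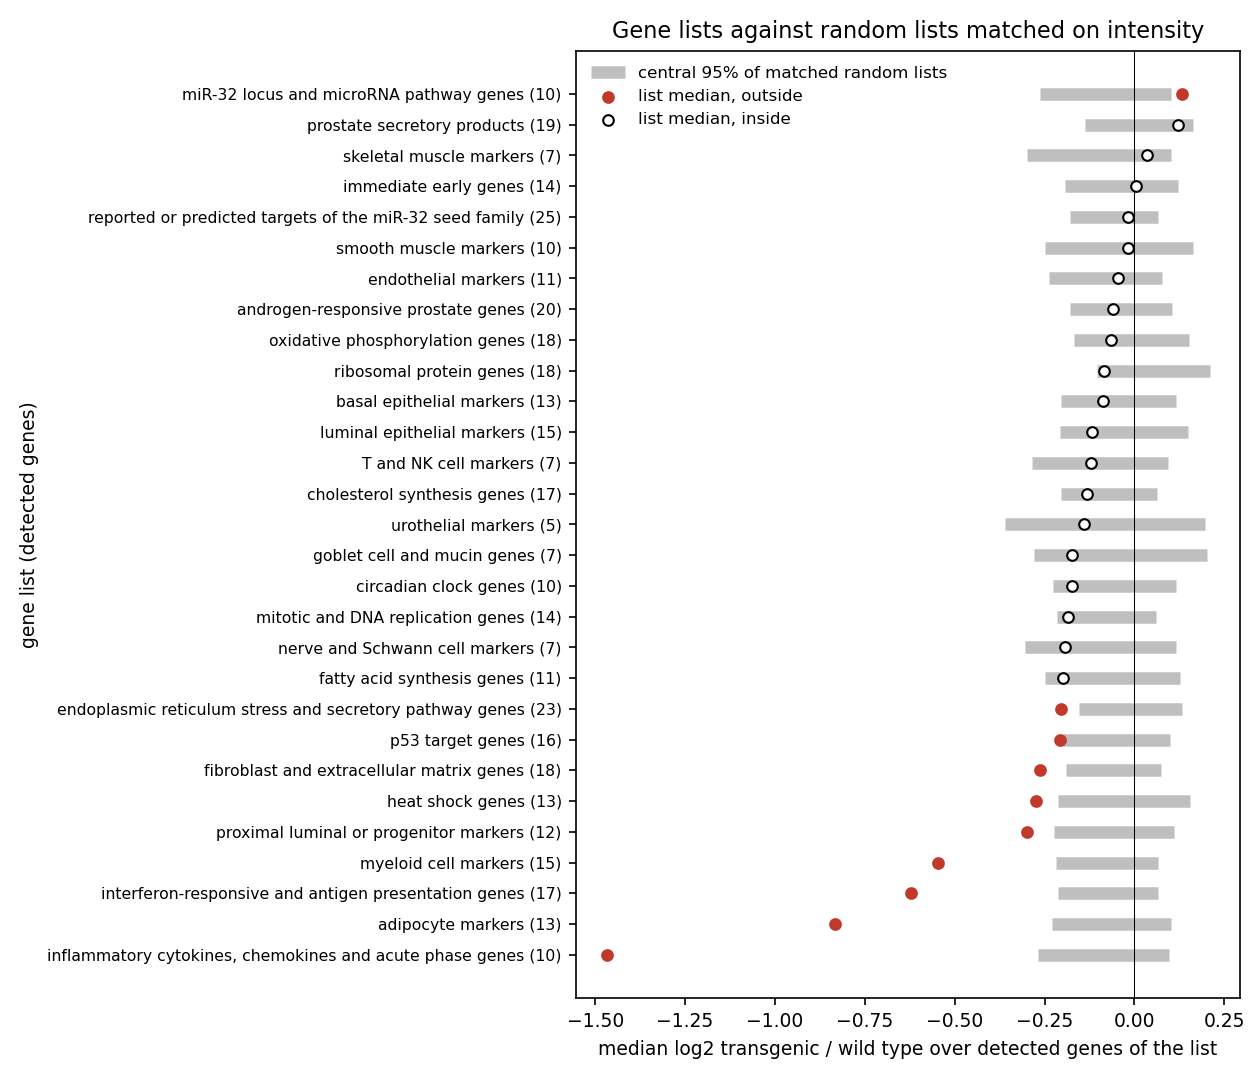
The median log2 ratio of transgenic to wild-type pool (horizontal axis) is shown for each of 29 gene lists with its number of detected genes, red where it lies outside the central 95% (grey bar) of 10000 random lists matched on intensity. Inflammatory (−1.47), adipocyte (−0.83), interferon and antigen presentation (−0.62) and myeloid lists (−0.55) lay farthest below their bars.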

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

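The tests of intensity trends and of further adipocyte, antigen presentation, interferon and acute phase genes were chosen after the results were seen. The tests on secretory, luminal, lobe and T and NK cell genes were set after the highest and lowest genes had been seen but before their own medians were computed, and the use of the SD over the arrays in judging them was added afterwards. For a list, that SD is of its medians on each array, which need not lie around the median of the gene means.

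A signal also appeared in probes that the gene comparison did not use. Of 2764 detected probes without a gene symbol, 40 were higher and 56 lower in the transgenic pool by the same size rule, and they remain unnamed here. Probes of an unnamed transcript were at −3.43, −3.27 and −2.27, the last of them not lower than Sbp (−3.18).

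Spink1, Sbp and Sbpl were lower on both arrays. A general loss of secretory transcripts would lower the other secretory genes too, but the median log2 ratio of the other 16 was 0.16. Of these, Spink5, 9530002B09Rik and Msmb were lower and most of the others neither. The median of the 16 was 0.25 and −0.11 on arrays 1 and 2 alone, and −0.01 with the scanner software's log ratios. With median centring it was −0.70, but the median of all detected genes was −0.57 there and Sbpl was at −3.22. A general loss of the size seen in Spink1, Sbp and Sbpl is argued against. Fewer luminal epithelial cells would lower luminal markers, whose median over 15 was −0.12 (−0.10 and −0.08 on arrays 1 and 2 alone). With median centring it was −0.96 (percentile 18.8 of matched random lists). Each of these is less than the loss of Sbpl (−2.06), the least lowered of the genes here. A different share of prostate lobes in the pools could still account for it. Pbsn and Msmb, which stood for the dorsal and lateral lobes, had a mean of −0.16 ± 0.79. Pbsn was at −0.32 and 1.39 on arrays 1 and 2, while Msmb was lower on both (−1.12 and −0.59), so their mean does not decide it. An effect of the transgene also stays open, as untested with 1 pool per genotype.

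Adipocyte genes were lower as a group. An intensity trend left by the normalization would move genes of equal intensity alike. The tables argue against it, because the list lay at or below percentile 0.47 of random lists matched on intensity on each array alone, without loess (median centring, −1.16), with the scanner software's log ratios (−1.58), without background subtraction (−0.80) and with the smaller offset, Aquantile or scaling. This could have come out otherwise, as the fibroblast and p53 lists moved inside the central 95% with median centring. For 13 further adipocyte genes outside the list the median lay at percentile 0.14, but at −0.13 and −0.23 on arrays 1 and 2 alone (percentiles 19.4 and 19.2). Less fat tissue around the transgenic prostates may account for it: the same 13 genes had a median of −0.33, which lies between the bounds of −0.58 and −0.2 set for it. Their array 1 median of −0.13 lies above those bounds, and 1 of the genes, Thrsp, was lower. Acly (0.47) and Fasn (−0.13) among them also belong to the fatty acid synthesis list, so these sets overlap. Fat at dissection and an effect of genotype cannot be told apart from these values, since either lowers adipocyte transcripts and each genotype was pooled once.

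Antigen presentation, interferon and acute phase genes were lower as groups. Against an intensity trend left by the normalization, the interferon and inflammatory lists lay at or below percentile 0.01 of matched random lists on each array and under the same alternatives. In addition, 29 further genes outside the lists had a median of −0.42, below all matched random lists on array 1 (percentile 0) and at percentile 0.04 on array 2. By the size rule 5 of them were lower, 0 were higher and the others were neither. Few of these further genes were acute phase genes. Fewer T and NK cells in the transgenic pool could contribute, with a median of −0.12 over 7 markers, between the bounds of −0.3 and −0.1. On arrays 1 and 2 alone it was −0.34 and −0.25, the first past the lower bound. It was −0.92 with the scanner software's log ratios, also past the lower bound, where the median of all detected genes was −0.11. With median centring it was −0.41, where that of all detected genes was −0.57. The explanation therefore stays open. No other cell type was weighed here. The myeloid markers had a median of −0.55, with all 15 means below 0 (percentiles 0 and 0.15 on arrays 1 and 2 alone). A different share of myeloid cells in the pools was not tested. Inflammation in 1 or a few of the wild-type mice cannot be told apart from an untested effect of genotype with 1 pool per genotype.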

How the results depend on the processing

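The rules on the mean of the arrays, on probes in place of genes and on probes that differ in sign were chosen after seeing the data. Against 95 higher and 136 lower genes, the counts were 149 and 239 with a normexp offset of 16, 248 and 625 with the scanner software's log ratios, and 2 and 554 with median centring. They were 25 and 37 at 2-fold, 248 and 446 for a mean of at least 1.5-fold, and 157 and 224 for probes. Detection in both pools left 76 lower genes and the deposited table gave 178 higher genes. The correlation across genes was 0.26 with the scanner software's ratios, against −0.03, and 0.24 in the deposited table. With 1 array left out, counts ranged from 544 to 845 higher and from 558 to 1570 lower, and lists outside the central 95% from 6 to 12. The stricter 2-fold rule and the looser rule on the mean move counts by construction, and for the others the cause was not tested.

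The other 35 values of these counts and correlations stayed within 1.5 times, or 0.1 in r. Leaving out genes whose probes differ in sign gave 71 higher and 128 lower. Median centring, which moved the median of detected genes to −0.57, put the microRNA pathway list at −0.23 and Klf2 at −0.12. The list lay at percentile 99.9 there, so its sign follows that shift and not a change among matched genes, and for Klf2 the cause was not tested. No other list outside the central 95% and no other called gene named by the rule changed sign under any alternative. Of 66 called genes named in the text, 18 lost their call with median centring, each of them a higher gene, and 7 with the scanner software's log ratios. Of these genes, 25 were not measured in the deposited table, each of them a lower gene. Among the genes measured there, 6 calls ended, 3 higher and 3 lower, and 19 lower and 16 higher calls were kept. Detection in both pools also left 25 lower genes unmeasured, so neither setting could check these lower calls. Calls ended for 6 genes with the mean over probes, 9 without background subtraction (H2-K1, Ccl5 and Ltf among them), 4 with scaling and 1 with the smaller offset. Of list medians, 220 values moved by less than the SD over the arrays and 113 by more, and of named genes 1447 and 234. No paired analysis was possible because the arrays hold 1 pool per genotype. The seed site result was not run, and leaving out saturated spots changes nothing because no spot was saturated. The weak Cy5 signal of array 2, which held the transgenic pool, limits how well low transcripts of that pool were measured.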

Other observations

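The genes in this part were chosen after their values were seen, and no test was run on them. Cox8b was at −1.39 ± 0.58, Cidea at −1.30 ± 0.04 and Ucp1, the uncoupling protein of brown fat, at −1.17 ± 0.34, each well above background in the transgenic pool on 1 of the 2 arrays. The genes of the interferon-inducible GTPases Tgtp1 and Igtp were at −1.21 ± 0.32 and −1.01 ± 0.50. The lysosomal protease gene Ctss was at −1.17 ± 0.12, and the secreted antiprotease genes Slpi and Wfdc18 were at −1.53 ± 0.74 and −1.54 ± 0.39. These genes, too, were well above background in the transgenic pool on 1 of the 2 arrays.

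Besides Ear1, the ribonuclease genes Rnase2a, Ang4 and Ear10 were at 1.46 ± 1.21, 1.41 ± 0.40 and 1.23 ± 0.06 in the transgenic pool. They were picked for their values, so nothing is said of their family, and near-identical relatives can share probe signal.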
